A study of Mus musculus with 15 samples.

How the data were processed

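Droplet single-cell RNA-seq (10x Genomics, 3' tags) of mouse brain and border tissue was analysed from 15 libraries, each a group of its own per the labels. The deposited tables hold counts: raw UMI counts per gene and cell barcode, which the authors made with Cell Ranger against mm10 (version not stated), 1 table per library. The values are whole numbers, and the number of barcodes in each table is the number of cells given in the labels. The table of 16-month WT brain holds 3999 of 27998 genes, so its sums are not a library depth, and it entered only comparisons over those genes. Ages of the other WT mice, the sex of the mice and the dissociation protocol of the WT libraries are not in the labels. Gene coordinates were taken from GENCODE vM21 on GRCm38, counted from 1.

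Cells were filtered and grouped in each of the 14 full libraries alone with scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9). A barcode was kept with at least 200 genes and at most 10% mitochondrial UMIs, which removed 149 of 62906. Doublets were scored with scrublet (expected share 5%), whose automatic threshold marked 0 to 17 cells per library, 67 in all. The highest scores were removed instead, at 0.8% per 1000 barcodes, 2546 cells in all, which left 60211. UMIs were scaled per cell and logged, 2000 variable genes and 30 principal components were taken, and a graph of 20 neighbours was partitioned with the Leiden method at a resolution of 1.0, which gave 284 clusters.

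Clusters were named by marker genes of 19 cell classes, listed before the data were examined, as were the 18 gene lists, the comparisons of tissues, protocols and genotypes and the rule for named genes. The scoring rule for the names was not fixed then. It went through 4 versions after the clusters had been seen, and the last changes were made while looking at which clusters became named, so the classes are partly post hoc. A cluster took a name when its score reached 0.4 and led the other scores by a margin. Against scores under 0.5 the margin was 0.05 within a lineage and 0.1 between lineages, and against higher scores 0.1 and 0.25. Between dendritic and plasmacytoid dendritic cells there was none. At least 3 markers had to be detected, and no other class could have more markers among the 10 leading genes. Clusters of low depth also needed a marker of their own there. Erythroid and choroid plexus epithelial cells had a rule of their own. The other clusters, 2.0 to 21.6% of the cells of a library, stayed unnamed and out of the comparisons of named classes over all genes, except that Spp1-led and Apoc1-led clusters were added as alternatives and the Apoc1-led cells of Irf8 control brain were compared with microglia-like cells. In comparisons over the 3999 genes each cell was assigned anew, cells of unnamed clusters included. Unnamed clusters with a BAM score of at least 0.4 and not below the microglia score held 11.8% of WT dura. They held 12.0% of Irf8 control and 13.2% of Irf8 deleter choroid plexus. Those with a microglia score of at least 0.4 and above the BAM score held 14.8% of 16-month APP/PS1 brain. Another class may have scored higher in these clusters. Names carry "-like" because they rest on these markers, among them P2ry12, Tmem119, Sall1, Sparc, Siglech, Gpr34, Olfml3, P2ry13, Fcrls, Slc2a5 and Cx3cr1 for microglia and Mrc1, Pf4, Ms4a7, Cbr2, Stab1, F13a1, Lyve1, Cd163, Folr2, Dab2, Apoe and Clec12a for border-associated macrophages (BAM).

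UMIs of a class with at least 20 cells were summed per library and given as CPM (UMIs scaled to a common sum) with exact Poisson 95% intervals, and shares of cells with exact binomial intervals. Tissues were compared over pairs of libraries with edgeR 4.0.16 (R 4.3.3), TMM scaling and a quasi-likelihood test with the pair as a term, at a Benjamini-Hochberg adjusted p of 0.05. Gene lists were tested with camera from limma 3.58.1, with a preset correlation of 0.01 and with an estimated one. The tissue test was tested on simulated data of the same size and depth, with 200 changed genes, the lowest expressed genes left out. Spread in these data followed its trend with expression. It did not vary between genes of like expression, and the tissue effect did not vary between pairs, so recovery may be too favourable. Between dura and choroid plexus the test recovered 96% of genes with a log2 change of 1 and 100% of those with 2, with 5.77% false calls. In microglia-like cells the test recovered 48% and 96%, with 7.1% false calls. Actinomycin D was tested in the same way in BAM-like cells over the pairs of dura and choroid plexus libraries with tissue as a term, chosen after the data had been seen, and that test recovered 85% and 100% of simulated changes with 7.96% false calls. Comparisons of 1 library against 1 have no test. For those 12 comparisons a list has the median log2 ratio of its members (pseudocount 5 CPM, members of at least 5 CPM) with an interval from 1000 Poisson resamples. Its percentile was taken among 10000 random lists matched on expression, and 95 of 181 medians lay outside the 2.5 to 97.5 percentiles. The text reports lists by that result, but not every list outside that range. List medians within single pairs of the tissue tests, taken in the same way, were chosen after the data had been seen. Lists were immediate early, heat shock, NF-kB and cytokine, homeostatic and disease-associated microglia, border macrophage core, MHC class I and II, type I interferon, complement, lysosome, sterol, lipid efflux, iron handling, cell cycle, monocyte-derived and Irf8-linked genes.

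Named genes were chosen by a rule. In tissue tests they are the 10 with the largest log2 change in each direction among genes past the threshold, with the same sign in every pair and at least 50 CPM in the higher tissue. In comparisons of 1 library against 1 they are the 10 with the largest log2 ratio in each direction among genes with at least 50 CPM and 30 UMIs in the higher library, ranked also by the smaller ratio where a contrast exists in 2 tissues or ages. Markers of other classes, sex-linked, ribosomal, mitochondrial and unnamed genes, and genes whose CPM is under 0.25 of that in the other cells, were left out of the ranking. Irf8, Fcgr1, Mrc1, P2ry12, Sall1, Tmem119, Trem2, Apoe, H2-Aa, Lyve1, Ccr2 and Clec12a were always added, with up to 4 members of each list with the largest change at 50 CPM or more. Results for some genes of the lists are not reported here. For 16-month WT brain, cells with at least 100 UMIs over the 3999 genes were assigned to the most similar class profile of the full brain libraries. Comparisons of APP/PS1 with WT whole brain over all genes, of the WT libraries with each other and of 16 with 9 months, and the minimum of 100 UMIs, were chosen after the data had been seen.

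Alternatives were DESeq2 1.42.0 (Wald test), no pair term, leaving out each pair, TMM scaling for single libraries, no ribosomal and mitochondrial genes, a pseudocount of 1 CPM, means of per-cell CPM, cells thinned to 2000 UMIs, all detected list members, Leiden resolutions of 0.5 and 2.0, cells classed cell by cell from their marker UMIs, doublet-scored cells kept and all barcodes. Naming margins doubled or at 0 and unnamed Spp1-led or Apoc1-led clusters added or removed were added after the data had been seen.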

Results

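Single-cell RNA was counted in droplet libraries (10x Genomics, UMI counts) of macrophage-rich tissue from mouse brain and its borders. The 15 libraries form 15 groups with 1 library each. WT C57BL/6JRj mice gave dura mater, choroid plexus, enriched subdural meninges and whole brain. Dura and choroid plexus were also prepared with a standard protocol and with actinomycin D, an inhibitor of transcription. Irf8fl/fl mice with CD64Cre (Irf8 deleter) and without it (Irf8 control) gave brain and choroid plexus. APP/PS1 mice, a model of amyloid deposition, gave brain at 9 and 16 months beside WT brain at 16 months. In 14 libraries the table held 27998 genes, 1834 to 6715 barcodes and 13353752 to 43701612 UMIs, with a median of 3370.0 to 6460.5 UMIs per barcode. The table of 16-month WT brain held only 3999 genes and 1655054 UMIs, so these sums are not its depth. There were no replicates within a group: intervals are exact 95% intervals that cover counting error only, and the tissue tests used pairs of libraries instead.

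Shares of border macrophages and microglia refer to the kept cells of a library and do not measure the composition of the tissue. No neuron, astrocyte or oligodendrocyte class was named in WT whole brain, and 8 of 3886 kept cells of WT choroid plexus were epithelial-like. Differences between libraries in the selection of cells were not examined. BAM-like cells, named after border-associated macrophages by genes such as Mrc1, Pf4 and Ms4a7, made up 63.2% (61.7 to 64.7) of the kept cells in WT choroid plexus, 30.9% (29.7 to 32.2) in WT dura, 23.03% (21.997 to 24.1) in subdural meninges and 0.737% (0.54 to 0.981) in whole brain. Microglia-like cells, named by genes such as P2ry12, Tmem119 and Sall1, made up 76.04% (74.96 to 77.1) in WT brain, 64.7% (63.5 to 65.8) in subdural meninges, 3.22% (2.68 to 3.82) in choroid plexus and 0.339% (0.204 to 0.529) in dura. Dura also held neutrophil-like (12.5%), dendritic-like (12.5%), monocyte-like (10.7%) and B-like cells (6.67%). In WT choroid plexus the next largest class was NK-like cells, at 13.6% (12.5 to 14.7). T-like cells took 23.04% (21.7 to 24.5) of the 9-month and 29.99% (28.6 to 31.4) of the 16-month APP/PS1 brain library, against 6.25% (5.66 to 6.88) in WT whole brain. By likeness over the 3999 genes of the 16-month WT table, 375 of its 2766 cells were closest to T cells, against 820 of 3529 and 1406 of 4038 in APP/PS1 at 9 and 16 months and 414 of 6244 in WT whole brain. Unnamed clusters held 2.0 to 21.6% of the cells of a library. With each cell classed from its own marker UMIs, the BAM-like share was 38.1% in WT choroid plexus, and at a cluster resolution of 2 it was 14.9% in subdural meninges.

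**Figure D1:**
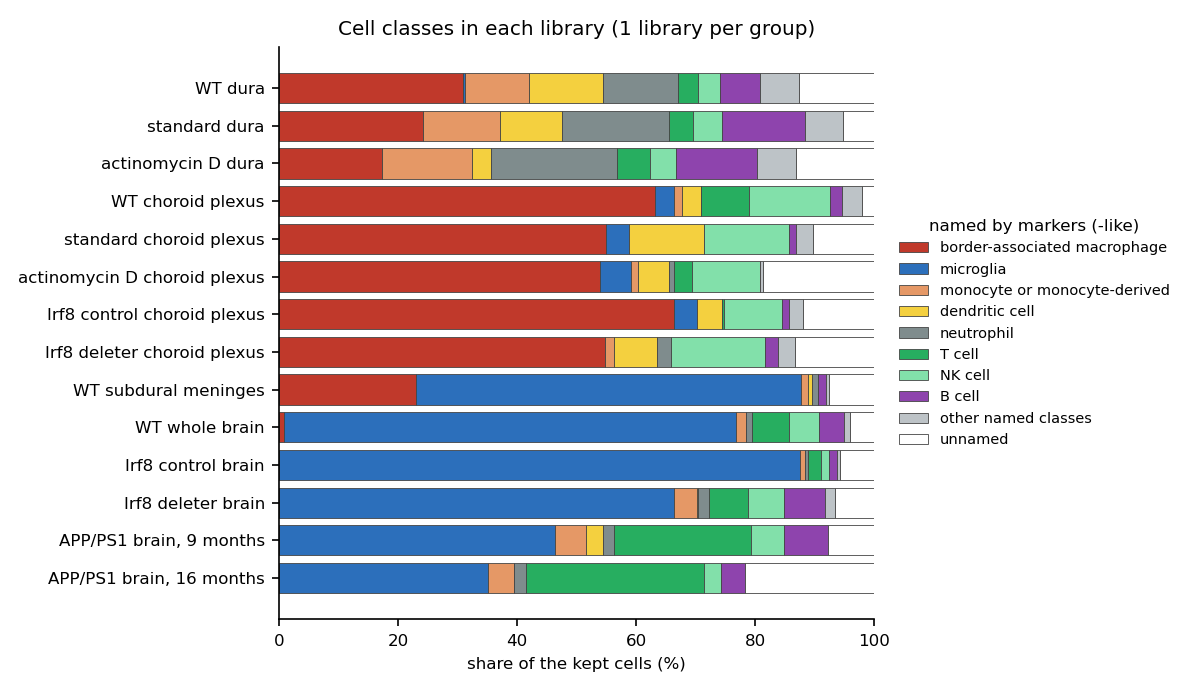
Share of the kept cells (%, horizontal axis) in each named class for 14 libraries, 1 bar per library. BAM-like cells fill 63.2% of WT choroid plexus and microglia-like cells 76.04% of WT whole brain.

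Whether macrophages of dura and choroid plexus differ was asked in BAM-like cells of 3 pairs of libraries (WT, standard protocol and actinomycin D), with 1734, 1131 and 617 cells in dura and 2456, 984 and 1239 cells in choroid plexus. The resistin-like gene Retnla had a mean of 120.04 CPM in dura and 0.05 CPM in choroid plexus, and Ear2, an eosinophil-associated ribonuclease, 77.7 and 0.51 CPM. The C-type lectins Cd209f (424 against 2.27 CPM, log2 change 7.45, SE 0.421) and Cd209g (177 against 1.21 CPM) and the hyaluronan receptor Lyve1 (101 against 3.94 CPM) rose in dura. So did the chemokine Ccl8 (1394 against 61.0 CPM, log2 change 4.38, SE 0.351), properdin (Cfp, 413 against 30.4 CPM) and the calcium-binding S100a6 (599.9 against 36.4 CPM). Lower in dura were the small heat shock protein Hspb1 (4.4 against 179.6 CPM), the matricellular Cyr61 (34.9 against 255 CPM), the leukocyte receptor Lilra5 (75.5 against 341 CPM) and the chemokine Ccl3 (424 against 2159 CPM). The microglial gene Tmem119 (97.96 against 315 CPM) fell in dura as well. In total 823 of 11001 genes rose and 751 fell in dura at an adjusted p of 0.05 (edgeR quasi-likelihood test with the pair as a term, Benjamini-Hochberg), and 3325 passed at an unadjusted p of 0.05. Adjusted p was 5.01e-05 for Retnla, 0.000287 for Cd209f, 0.000535 for Lyve1, 0.000788 for Ccl8, 0.00119 for Hspb1 and 0.00211 for Ccl3 in that edgeR test (Benjamini-Hochberg). Leaving out the actinomycin D pair gave 641 genes and leaving out the WT pair 1037, while the DESeq2 Wald test gave 979 and edgeR without the pair term 684. Without the pair term Hspb1, Cyr61 and Ccl3 no longer passed. Library scaling moved the log2 changes by -0.12 relative to ratios of CPM.

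**Figure D2:**
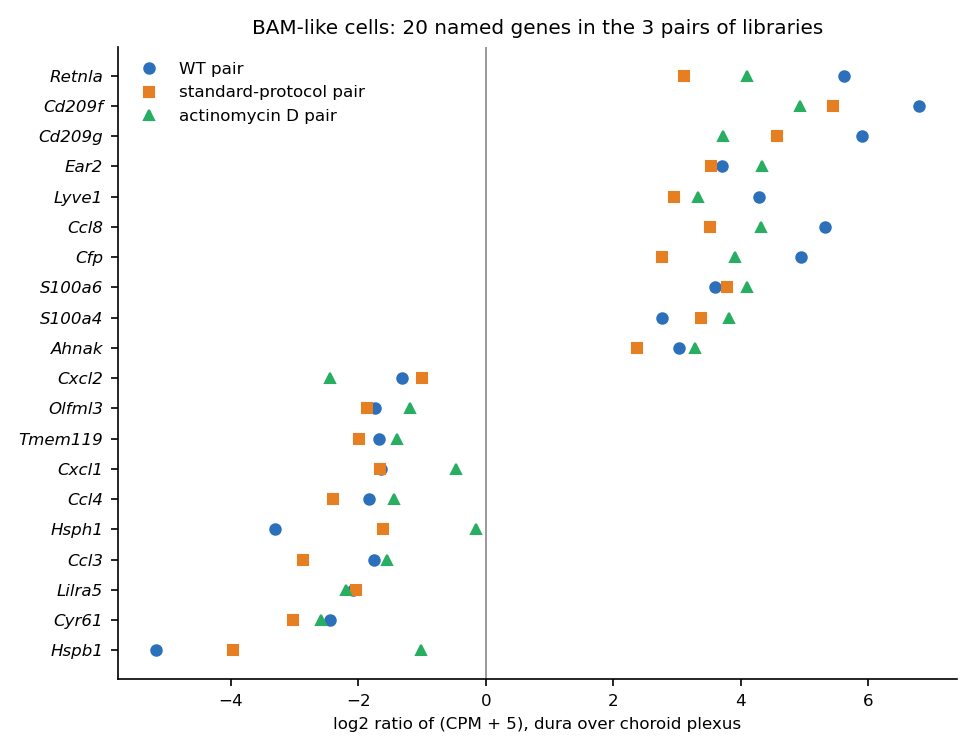
Log2 ratio of (CPM + 5) in BAM-like cells, dura over choroid plexus (horizontal axis), for 20 genes, with 1 point per pair of libraries. Retnla has ratios of 5.61, 3.11 and 4.09 in the WT, standard and actinomycin D pairs, and Hspb1 -5.17, -3.96 and -1.02.

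The monocyte-derived list rose in dura: 11 of 11 tested members passed, among them Plac8 (log2 change 4.54), Chil3 (4.28), Ly6c2 (4.004) and S100a6 (3.89). The chemokine receptor Ccr2 (325 against 62.6 CPM) and the galectin Lgals3 (2.64) were further members of the list. Camera with a preset correlation of 0.01 gave the list an adjusted p of 6.26e-13, and the adjusted p was 0.275 with an estimated correlation. Of 25 border macrophage core genes, 14 rose and 1 fell (15 and 1 when adjusted over the list alone). The folate receptor Folr2 reached a log2 change of 2.98 and the mannose receptor Mrc1 0.57, and both had served to name the class. The core list had a camera adjusted p of 6.53e-08, and an adjusted p of 0.665 with an estimated correlation. Of 10 iron handling genes 3 rose, including the iron exporter Slc40a1 (log2 change 2.21) and the haemoglobin receptor Cd163 (1.16), and the metal transporter Slc11a1 fell (-0.73). Of 9 lipid efflux genes 4 rose, such as the phospholipid transfer protein Pltp (1.57), and 2 fell, including Apoe (39447 against 56131 CPM). Of 10 complement genes 3 rose, and the anaphylatoxin receptors C3ar1 (-0.78) and C5ar1 (-0.65) fell. Without the actinomycin D pair Mrc1, Apoe, C5ar1 and Slc11a1 no longer passed, without the standard pair Apoe and C5ar1, and without the pair term Mrc1, Apoe, C5ar1 and Cd163. Apoe did not pass at a resolution of 2.0 or with doublet-scored cells kept either, nor did Apoe and C5ar1 with naming margins doubled, where the actinomycin D pair dropped out. The iron, lipid efflux and complement lists had camera adjusted p of 0.23, 0.283 and 0.527, and adjusted p of 0.665, 0.677 and 0.861 with an estimated correlation. Markers of other cells moved alongside: 9 of 10 neutrophil, 6 of 7 B cell, 4 of 4 erythroid, 6 of 14 dendritic and 9 of 11 monocyte markers rose in dura, whereas 7 of 7 choroid plexus epithelial markers fell. The monocyte markers share genes such as Ccr2, Ly6c2, Plac8 and Chil3 with the monocyte-derived list.

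Homeostatic microglia and stress-linked lists were higher in choroid plexus, with smaller differences in the stress-linked lists of the actinomycin D pair. In the WT, standard and actinomycin D pairs the median log2 ratio of dura over choroid plexus was -0.47, -0.78 and -0.62 for homeostatic, -0.60, -0.69 and -0.28 for immediate early, -1.32, -1.16 and -0.50 for NF-kB and cytokine and -2.95, -1.25 and -0.03 for heat shock genes. Hsph1 had ratios of -3.31, -1.61 and -0.15 and Rhob -1.47, -1.39 and -0.31, whereas Cxcl2 had -1.32, -0.99 and -2.45. The difference between pairs was not tested. Of 19 homeostatic microglia genes 14 fell in dura (15 fell when adjusted over the list alone), such as Olfml3 (165 against 490.5 CPM, log2 change -1.75, SE 0.151) and Siglech (-1.13). P2ry12 fell too (-0.67). The list holds the microglia markers, of which 9 of 11 tested fell in dura. Microglia-like cells made up 3.22% of WT choroid plexus and 0.339% of WT dura, and a mixture with their RNA was not examined in BAM-like cells. The homeostatic list had a camera adjusted p of 7.25e-08, and the adjusted p was 0.275 with an estimated correlation. Of 18 NF-kB and cytokine genes 12 fell, also 12 when adjusted over the list alone, with Ccl4 at -2.05, Cxcl1 at -2.02 and Cxcl2 at -1.74. Their camera adjusted p was 0.000184, and the adjusted p was 0.275 with an estimated correlation. Of 21 immediate early genes 10 fell (14 when adjusted over the list alone), including Rhob (-1.21), Jun (-1.09) and Nr4a1 (-1.08). Here the camera adjusted p was 1.55e-06, and the adjusted p was 0.442 with an estimated correlation. Of 11 heat shock genes 2 fell, including Hsph1 (-2.23), and 11 fell when adjusted over the list alone, while the chaperone Hspa1a (341 against 3704 CPM) did not pass over all genes. Camera gave the chaperones an adjusted p of 0.000848, and the adjusted p was 0.677 with an estimated correlation. Of 15 sterol genes 6 fell (10 when adjusted over the list alone), and of 13 MHC class I genes 4 fell, such as H2-Q7 (-1.19) and H2-Q4 (-1.06). The sterol and MHC class I lists had camera adjusted p of 8.99e-05 and 0.00901, and adjusted p of 0.275 and 0.677 with an estimated correlation. Without the actinomycin D pair P2ry12 and Nr4a1 no longer passed, and without the WT pair Hsph1, Cxcl2, Rhob and Nr4a1. Without the pair term Ccl4, Cxcl1, Cxcl2, P2ry12, Rhob, Jun, Nr4a1, Hsph1, H2-Q7 and H2-Q4 did not pass. Hsph1 also failed to pass by the Wald test, at resolutions of 0.5 and 2.0, with doublet-scored cells kept and with naming margins of 0.

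MHC class II was at a similar level in dura and choroid plexus. H2-Aa had a mean of 8256 CPM in dura and 8579 CPM in choroid plexus, Cd74, the invariant chain, 26979.5 and 30297 CPM, and 1 of 10 members passed the edgeR test. The median log2 ratio was -0.17, 0.33 and -0.15 in the WT, standard and actinomycin D pairs for MHC class II and 0.90, -0.20 and -0.26 for interferon genes. Of 20 type I interferon genes 1 rose, and Ifitm3 (1903 against 1063 CPM) did not pass. None of 18 cell cycle genes passed the edgeR test. Of 23 lysosome genes 5 fell, such as the cathepsin Ctss (-0.72). Of 27 disease-associated microglia genes 6 rose and 2 fell, with Lgals3, the chemokine Ccl6 (2.18) and the growth factor Igf1 (1.004) rising. Irf8, a transcription factor of the myeloid lineage, stood at 275 CPM in dura and 375 CPM in choroid plexus (log2 change -0.56, SE 0.097, adjusted p = 0.013 by the edgeR test, Benjamini-Hochberg). Of 12 Irf8-linked genes 1 rose, Ifitm6 (3.80), and 3 fell, including the receptor Csf1r (-0.75). Without the actinomycin D pair Irf8, Csf1r and Ctss no longer passed, without the standard pair Ctss, with naming margins doubled (no actinomycin D pair) Csf1r and Ctss, and at a resolution of 2.0 Irf8. The camera adjusted p was 0.939 for MHC class II, 0.527 for interferon, 0.309 for cell cycle, 0.0643 for lysosome, 0.529 for disease-associated and 0.23 for Irf8-linked genes, and with an estimated correlation the adjusted p was 0.981, 0.915, 0.861, 0.74, 0.743 and 0.72.

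A small population of microglia-like cells in choroid plexus was compared with microglia-like cells of brain in 2 pairs of libraries, WT (125 against 4748 cells) and Irf8 control (163 against 4817 cells). The Irf8 deleter pair had been planned too, but it was left out because deleter choroid plexus held 0 cells named microglia-like. The lipid carrier Apoe stood at 36814 CPM in choroid plexus and 1332 CPM in brain (log2 change 5.11, SE 0.358), Apoc1 at 234 and 3.6 CPM, and the cholesterol hydroxylase Ch25h at 144 and 0.71 CPM. Osteopontin (Spp1, 279 against 3.57 CPM, log2 change 6.75, SE 0.245), the cystatin Cst7 (366 against 14.4 CPM), the cytokine Il1b (1082 against 33.3 CPM) and the chemokine Cxcl2 (2612 against 24.1 CPM) rose too. Genes that fell in choroid plexus were the uroplakin Upk1b (5.91 against 81.9 CPM), the thioredoxin-like Tmx4 (54.4 against 430.5 CPM), the adenosine receptor Adora3 (21.5 against 162 CPM) and the endothelial-type Ecscr (60.98 against 413 CPM). The purinergic receptor P2ry12 (698 against 4226 CPM), Tmem119 (669 against 2955 CPM) and the transcription factor Sall1 (31.4 against 134 CPM) fell as well, although they had served to name the class. By the edgeR quasi-likelihood test 1501 of 11181 genes rose and 1060.0 fell, with Benjamini-Hochberg adjusted p of 4.96e-17 for Apoe, 2.94e-28 for Spp1 and 1.14e-09 for P2ry12. With 1 residual degree of freedom those p-values rest on a spread shared across genes (50.01 prior degrees of freedom). The DESeq2 Wald test passed 1014 genes (799 higher and 215 lower), the fit without the pair term 1297 and cells classed cell by cell 1253. With cells classed cell by cell the Irf8 deleter pair entered too (40 against 2714 cells). In that setting Apoe, Apoc1, Ms4a7, Hspa1a and Fth1 did not pass, and the effects of classing and of the added pair were not separated. Without the pair term Hspa1a and Hmox1 did not pass, and with doublet-scored cells kept H2-Aa did not. The median depth was 10289 and 9475 UMIs per choroid plexus cell and 3656.5 and 3610.0 per brain cell, and library scaling moved the log2 changes by 0.42 relative to ratios of CPM.

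Among the lists, 19 of 27 disease-associated microglia genes rose in choroid plexus (22 when adjusted over the list alone). The growth factor Igf1 reached a log2 change of 5.65 and Cst7 5.06, whereas the lipid receptor Trem2 (1796 against 2837 CPM) did not pass. Of 20 border core genes 18 rose, for example Pf4 (1649.7 against 8.52 CPM), Ms4a7 (299 against 2.72 CPM) and Folr2 (5.82). Of 18 NF-kB and cytokine genes 16 rose, such as Ccl7 (5.27), and of 20 homeostatic genes 12 fell (15 when adjusted over the list alone), such as P2ry13 (-1.89) and Slc2a5 (-1.72). Camera adjusted p was 5.38e-12 for the disease-associated, 2.74e-11 for the border core, 8.41e-11 for the NF-kB and 3.45e-06 for the homeostatic list, and with an estimated correlation the adjusted p was 0.498, 0.595, 0.498 and 0.498. Of 10 MHC class II genes 5 rose, with H2-Aa at 874 against 39.5 CPM and Cd74 at 3144 against 158 CPM, and 7 of 13 MHC class I genes rose, such as H2-Q7 (2.39). Iron handling was mixed, with 6 of 10 genes rising, such as the haem oxygenase Hmox1 (2.39) and the ferritin chain Fth1 (1.88), and Slc40a1 falling (-1.54). Also rising were 10 of 11 heat shock genes such as Hspa1a (2.01), 10 of 20 interferon genes such as Ifitm3 (2.61), 11 of 15 sterol genes, 11 of 17 cell cycle genes such as Stmn1 (1.77), 7 of 11 monocyte-derived, 7 of 21 immediate early, 7 of 23 lysosome and 5 of 9 complement genes. The pairs differed in size in some lists: in WT and Irf8 control the median log2 ratio was 1.45 and -0.05 for heat shock genes (2.30 and 0.79 for Hspa1a), -0.53 and 0.43 for immediate early and -0.21 and 0.27 for MHC class II genes. These are ratios of CPM without library scaling, which moved the fitted log2 changes by 0.42. The sign of a median of about that size or smaller therefore gives no direction. Of 8 lipid efflux genes 4 rose and 3 fell, and of 13 Irf8-linked genes 5 rose and 3 fell. Camera passed 15 of the lists in this comparison, and none of them passed with an estimated correlation, as also for the 8 lists passed between dura and choroid plexus. The complement gene C1qa (7109 against 11085 CPM) and Irf8 (483 against 721 CPM) did not pass. Markers of choroid plexus epithelium rose (2 of 2), as did 4 of 7 monocyte markers, and 5 of 7 neutrophil markers fell. By ratios of CPM without library scaling, the monocyte markers had a median of -0.315 in the WT pair (4 of 6 lower) and 2.05 in the Irf8 control pair (4 of 4 higher).

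BAM-like cells of choroid plexus and brain could not be put to the designed test, because only WT brain held a named BAM-like cluster (46 cells). In that single WT pair Lyve1 was lower in choroid plexus than in brain (2.54 against 526 CPM), as were Cd209f (1.46 against 366 CPM) and Folr2 (32.2 against 571 CPM), whereas H2-Aa (8775 against 714 CPM) and Cd74 (32519 against 2685 CPM) were higher in choroid plexus. The border core list had a median log2 ratio of -1.43 (-1.57 to -1.29), with 22 of 24 members lower, and MHC class II 2.23 (2.07 to 2.63). T cell and neutrophil markers were lower in choroid plexus (medians -2.19 and -2.69). At a cluster resolution of 0.5 the directions turned, with medians of 0.017 for the core list and -0.44 for MHC class II and log2 ratios of -0.38 for H2-Aa and -0.14 for Cd74. With cells classed cell by cell 3 pairs remained, in which 152 of 9895 genes rose in choroid plexus and 103 fell by the edgeR test (Benjamini-Hochberg), and 1062 passed at an unadjusted p of 0.05. Those pairs were WT, Irf8 control and Irf8 deleter, with 60, 29 and 177 brain cells.

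Actinomycin D was set against the standard protocol to ask which transcripts arise during tissue dissociation. Immediate early genes, induced within minutes of stimulation, were lower with actinomycin D in all 21 of 21 measured members, in BAM-like cells of dura (median log2 ratio -3.75, interval -3.90 to -3.66), BAM-like cells of choroid plexus (-4.14, -4.26 to -4.06) and microglia-like cells of choroid plexus (-4.73, -5.03 to -4.57). Fos, a subunit of the AP-1 transcription factor, stood at 112 CPM (102 to 122) against 2771 CPM (2734 to 2808) in dura BAM-like cells and at 148 against 5241 CPM in those of choroid plexus. Atf3, another stress-induced factor, stood at 25.7 against 1259 CPM in dura and Egr1 at 17.2 against 1013 CPM in choroid plexus. Cytokine genes were lower too: the NF-kB and cytokine list had medians of -2.51 (17 of 17 members lower), -3.23 (17 of 17) and -4.95 (17 of 18). Cxcl2 stood at 7.79 against 1621 CPM in dura BAM-like cells, Ccl3 at 86.4 against 4039 CPM in choroid plexus BAM-like cells, and Ccl4 at 30.4 against 8413 CPM in choroid plexus microglia-like cells. Heat shock genes had medians of -0.99, -1.77 and -1.48, with the inducible chaperone Hspa1a at 29.6 against 3895 CPM in choroid plexus BAM-like cells. The haem oxygenase Hmox1 was lower in all 3 (log2 ratios -2.21, -2.93 and -3.65). Irf8 had log2 ratios of 0.08, -0.07 and 0.11, and MHC class II medians of -0.03, 0.42 and -0.01.

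Higher with actinomycin D were Maf, a macrophage transcription factor (503 against 218 CPM in dura and 398 against 189 CPM in choroid plexus BAM-like cells), the scavenger receptor Stab1 (560.3 against 298 CPM and 466 against 232 CPM) and the glycosyltransferase Ogt (log2 ratios 1.42 and 1.03). The border core list had medians of 0.33 in dura and 0.33 in choroid plexus BAM-like cells, and -0.84 in microglia-like cells, where Pf4 stood at 171 against 714 CPM and Apoe at 16426 against 39091 CPM. In core members that were not naming markers the medians were 0.09 (8 of 14 higher, against 0.09 for all genes), 0.33 and -0.81, so the dura value rests on markers of the class. Of the homeostatic list 19 of 20 members were higher in those microglia-like cells (118 against 69 cells), with a median of 0.57 (0.32 in the 8 that were not naming markers), such as P2ry12 (1396 against 679 CPM) and Sall1 (65.5 against 25.6 CPM). Fitted as a mixture of brain microglia-like and BAM-like profiles, these cells had a BAM-like share of 8.08% with actinomycin D and 43.4% with the standard protocol, and monocyte markers were lower (median -1.36), so the core and homeostatic values are not separated from a mixture. Cell cycle genes were lower in BAM-like cells of choroid plexus (median -2.04, 18 of 18), with Top2a at 3.89 against 59.99 CPM and Stmn1 at 44.6 against 298 CPM, and of dura (-0.45, 18 of 18). At a cluster resolution of 0.5 the dura cell cycle median was 0.80, and with cells classed cell by cell the core median in microglia-like cells was 0.11 and the log2 ratio of Pf4 0.69. With naming margins of 0, P2ry12 and the homeostatic list both had -0.13 there, and the interferon list 0.005. Interferon genes had medians of 0.31 and 0.50 in BAM-like cells, with Ifit3 at 150.4 against 58.3 CPM in choroid plexus, but -0.80 in microglia-like cells (15 of 19 lower). Erythroid (median 2.22) and neutrophil markers (1.19, 10 of 10) were higher in dura BAM-like cells with actinomycin D, and mast cell (-2.38) and neutrophil markers (-0.59) were lower in those of choroid plexus. Apart from MHC class II in dura and in microglia-like cells the medians of whole lists named for actinomycin D lay outside the central 95% of 10000 random lists matched on expression.

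A test of actinomycin D in BAM-like cells over the pairs of dura and choroid plexus libraries was chosen after the data had been seen. With tissue as a term, edgeR passed 562 of 10959 genes as lower and 162 as higher with actinomycin D (quasi-likelihood test, Benjamini-Hochberg), and 2454 passed at an unadjusted p of 0.05. Lower were 21 of 21 immediate early, 15 of 17 NF-kB and cytokine, 8 of 11 heat shock and 3 of 18 cell cycle genes, and higher were 4 of 20 interferon and 2 of 25 border core genes. Erythroid markers were higher in 4 of 4. Of 19 homeostatic and 10 complement genes 2 each were higher and 1 each lower. Fos had a log2 change of -4.99 (SE 0.172, adjusted p = 7.52e-05 by the edgeR test, Benjamini-Hochberg, and 2.88e-156 to 0.0493 over the alternatives). The p-values rest on 1 residual and 4.95 prior degrees of freedom. They measure how far dura and choroid plexus changed alike, since each tissue had 1 library per protocol. The protocol itself was not replicated. The DESeq2 Wald test passed 395 genes. Without the tissue term edgeR passed 52, with 10 of the immediate early, 1 of the NF-kB and none of the heat shock genes among them, and 1217 at an unadjusted p of 0.05. Camera passed 8 of 17 lists with the preset correlation and none with an estimated one. Microglia-like cells had a single pair and no test.

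**Figure D3:**
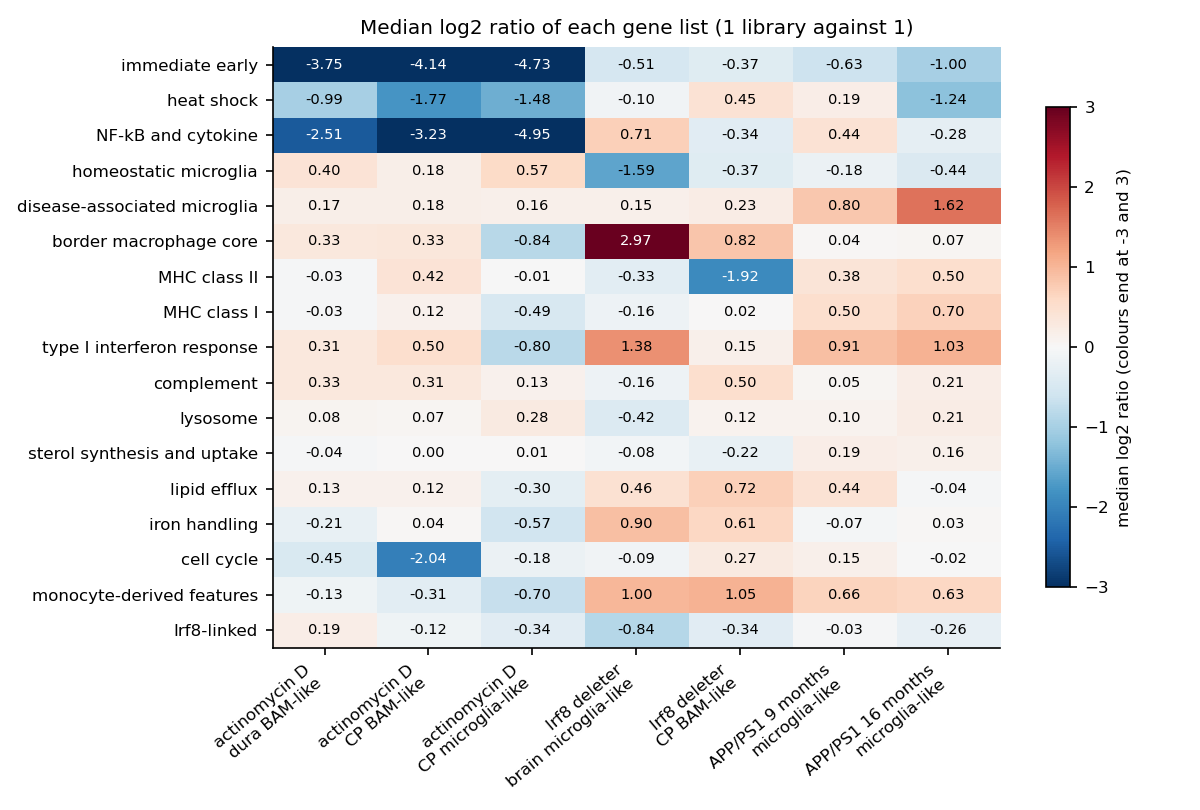
Median log2 ratio of 17 gene lists (vertical axis) in 7 comparisons of 1 library against 1 (horizontal axis), with the value printed in each field. Immediate early genes have medians from -3.75 to -4.73 with actinomycin D, and the border macrophage core list has 2.97 in brain microglia-like cells of the Irf8 deleter.

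The deletion of Irf8 was examined in microglia and in border macrophages. Irf8 itself (ENSMUSG00000041515.10, chromosome 8, 120736358 to 120756694, plus strand, GRCm38) stood at 326 CPM (317 to 335) in deleter against 729 CPM (717 to 742) in control microglia-like cells of brain, and at 137 CPM (128 to 147) against 337 CPM (327 to 346) in BAM-like cells of choroid plexus. Tags lie near the 3' end of the transcript and can fall outside the deleted part, so Irf8 counts do not measure the loss of protein. Cells with an Irf8 UMI made up 66.0% of deleter and 90.4% of control brain microglia-like cells (median depth 3464 and 3610.0 UMIs), against 9.8% and 22.9% of T-like cells (3120.0 and 3909 UMIs), where the gene serves as background. In choroid plexus BAM-like cells these Irf8 shares were 45.4% and 73.7% (4638 and 4879.5 UMIs). Fcgr1, which encodes CD64, the locus of the Cre, stood at 85.4 against 512 CPM in brain and 109 against 414 CPM in choroid plexus.

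Brain microglia-like cells of the deleter had less of the homeostatic profile and carried transcripts typical of border macrophages. Sall1 stood at 0.63 CPM (0.3 to 1.15) against 146 CPM (140.5 to 152), P2ry12 at 471 against 5106 CPM, the fructose transporter Slc2a5 at 37.6 against 653 CPM, the matricellular Sparc at 372 against 3801 CPM and the adhesion receptor Adgrg1 at 11.2 against 382 CPM. All 20 of 20 homeostatic genes were lower, with a median log2 ratio of -1.59 (-1.61 to -1.57). The 8 members that had not served to name the class had a median of -1.18. Apoe stood at 156209 against 1303 CPM, Apoc1 at 4028 against 6.39 CPM, the platelet factor Pf4 at 2584 against 10.7 CPM, Ms4a7 at 723 against 3.17 CPM and the lectin Clec4n at 363 against 1.11 CPM. All 18 of 18 border core genes were higher, with a median of 2.97 (2.87 to 3.04) over members of at least 5 CPM, 1.87 over all detected members and 4.68 with a pseudocount of 1 CPM, and the 9 that were not naming markers had 2.72. The type I interferon list was higher in 19 of 19 members (median 1.38, 1.19 to 1.47), with Ifi204 at 99.9 against 14.6 CPM and Irf7 at 53.8 against 10.6 CPM. Iron handling (median 0.90), monocyte-derived (1.01), NF-kB and cytokine (0.71) and lipid efflux (0.46) lists were higher and immediate early genes lower (-0.51), with the ferritin chain Fth1 at 6968 against 2683 CPM and Pltp at 72.95 against 1.95 CPM. Irf8-linked genes had a median of -0.85, with the actin-linked Aif1 lower (108 against 1022 CPM) and the oxidase subunit Cybb higher (125 against 3.5 CPM). The peptide loader H2-DMa was lower (30.4 against 359.9 CPM), as were Tmem119 (1630.3 against 3476 CPM), Trem2 (1886 against 2995 CPM) and C1qb (3492 against 11061 CPM).

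The median log2 ratio of all 9348 genes in this brain comparison was -0.21. Microglia-like cells were 87.6% (86.7 to 88.5) of control and 66.4% (65.2 to 67.6) of deleter brain cells, and T-like cells 2.15% and 6.57%. In the deleter, clusters of the class led with Apoc1 or Apoe beside Tmem119 and Olfml3. Neutrophil (median 1.58), plasmacytoid dendritic (0.92) and monocyte markers (0.76) were higher in the deleter class. With naming margins doubled, no microglia-like cluster was named in the deleter brain.

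BAM-like cells of choroid plexus in the deleter had less MHC class II and more of the border core genes. H2-Aa stood at 2269 CPM (2231 to 2307) against 10945 CPM (10892 to 10998), H2-Ab1 at 2351 against 12789 CPM and Cd74 at 9008 against 39223 CPM, and 10 of 10 MHC class II genes were lower (median log2 ratio -1.92, -1.97 to -1.86). The NK-type receptor Klra2 (6.01 against 142 CPM), the cytokine Il1b (140.4 against 1027 CPM), the chemokine receptor Ccr1 (23.9 against 185 CPM), the adhesion molecule Vcam1 (22.2 against 147 CPM) and the chemokine Ccl12 (418 against 1807 CPM) were lower too. Higher were the lectins Clec4d (111 against 4.88 CPM) and Clec4n (932 against 96.5 CPM), the complement receptor Vsig4 (139 against 10.4 CPM), Lyve1 (113 against 12.04 CPM), the coagulation factor F13a1 (779.6 against 178 CPM) and the carbonyl reductase Cbr2 (838 against 273 CPM). In the border core list 21 of 22 members were higher (median 0.82, and 0.76 in the 11 that were not naming markers). The monocyte-derived list was higher (median 1.05, 0.99 to 1.28, 6 of 9 members higher), as for S100a6 (119 against 18.3 CPM), whereas the monocyte markers had a median of 0.03, inside the central 95% of random lists. Lipid efflux (median 0.72), iron handling (0.61), complement (0.50) and heat shock (0.45) lists were higher, with Slc40a1 at 134 against 24.01 CPM, Hmox1 at 432 against 124 CPM and the cholesterol exporter Abca1 at 157 against 67.5 CPM. Immediate early (-0.37), NF-kB and cytokine (-0.34), Irf8-linked (-0.34), sterol (-0.22) and homeostatic (-0.37) lists were lower, with Atf3 at 318 against 1121 CPM and Tmem119 at 187 against 391 CPM, although the 8 homeostatic members that were not naming markers had a median of 0.27. Neutrophil (median 1.98) and erythroid markers (1.76) were higher in the deleter cells, and the median of all 8951 genes was 0.19.

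**Figure D4:**
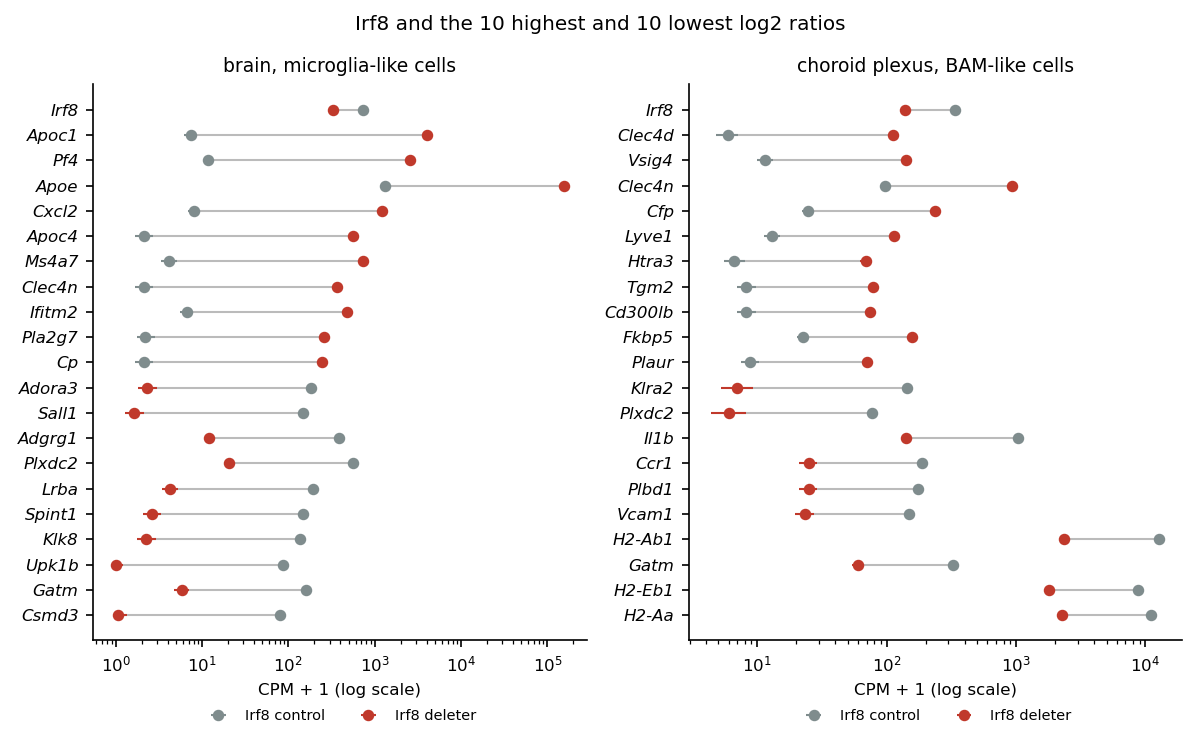
CPM + 1 (log scale, horizontal axis) of Irf8 and of the 10 highest and 10 lowest genes in Irf8 deleter and control, with bars for the 95% Poisson interval. Apoe reaches 156209 CPM in deleter brain microglia-like cells against 1303 CPM in control, and H2-Aa 2269 against 10945 CPM in choroid plexus BAM-like cells.

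In APP/PS1 brain, microglia were compared with WT microglia. Over all genes the only WT reference was whole brain of unstated age (4748 microglia-like cells, against 1639 at 9 and 1419 at 16 months). Against it the disease-associated microglia list was higher in 25 of 26 members at 9 months (median log2 ratio 0.80, 0.75 to 0.84) and in 27 of 27 at 16 months (1.62, 1.46 to 1.66). Cst7, an inhibitor of cathepsins, stood at 489 CPM (471 to 507) at 9 months, 838 CPM (815 to 860.3) at 16 months and 17.9 CPM (16.1 to 19.97) in WT. Apoe stood at 3563, 10843 and 1362 CPM, the lipoprotein lipase Lpl at 97.6, 197 and 27.4 CPM, and the ketone body receptor Hcar2 at 58.2, 101 and 7.83 CPM. At 16 months Spp1 was at 132 against 4.81 CPM in WT, Igf1 at 86.4 against 1.57 CPM and the fatty acid carrier Fabp5 at 118 against 5.24 CPM. Homeostatic genes were lower at 16 months (median -0.44, 20 of 20), as for P2ry12 (2019 against 3346 CPM), and the median at 9 months, -0.18, lay inside the central 95% of random lists. Trem2 stood at 3120.4 and 3968 against 2678 CPM. Type I interferon genes were higher at 9 and 16 months (medians 0.91 and 1.03), with Ifi27l2a at 305 and 415 against 74.8 CPM and Ifitm3 at 198 and 227 against 76.4 CPM. MHC class I was higher too (0.50 and 0.70), with H2-Q7 at 104 and 94.6 against 27.8 CPM. Over 3 measured interferon genes, 16-month WT brain was also higher than WT whole brain (median 0.77). Against 16-month WT brain these 3 genes had medians of 0.50 at 9 and 1.01 at 16 months.

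Against WT whole brain the immediate early list had medians of -0.63 at 9 and -1.0 at 16 months, with Fos at 1942 and 2644 against 7179 CPM. Against 16-month WT brain the 3 measured members were higher instead, with medians of 0.36 at 9 and 0.47 at 16 months, inside the central 95% of random lists. Between the WT libraries, 16 months against unstated age, these members had a median of -1.44. Heat shock genes had a median of -1.24 at 16 months against WT whole brain, where Hspa1a stood at 42.5 against 573 CPM, whereas at 9 months it stood at 1299 CPM. Against 16-month WT brain the 3 measured heat shock genes were higher, with medians of 0.63 at 9 and 0.39 at 16 months. The 9-month median lay outside the central 95% of random lists and the 16-month median inside. Between the WT libraries their median was -0.45, also inside. The values that follow are against WT whole brain. T cell (medians 1.15 and 1.32) and dendritic markers (0.31 and 0.48) were higher in the microglia-like class, as were MHC class II (0.38 and 0.50) and monocyte-derived genes (0.66 and 0.63), and neutrophil markers were higher at 9 months (1.11). The MHC class II medians were negative at both ages when doublet-scored cells were kept. At 16 months the median of all 9200 genes was -0.16.

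Against the age-matched 16-month WT brain only part of the genes could be compared, and cells were taken as microglia-like by their likeness over the 3999 genes of that table. The disease-associated list had 3 measured members there, B2m, Ctsz and Cst7, with a median of 0.76 (0.74 to 0.78) at 16 months and 0.44 (0.42 to 0.46) at 9 months. Without cells closest to an Spp1-led cluster the median at 16 months was 0.58. Markers of other cells moved too, with 3 measured members each: neutrophil markers were lower (medians -2.22 and -1.12) and choroid plexus epithelial markers higher at 9 months (3.25). Cst7 stood at 10519.9 and 3074 CPM of those genes against 392.3 CPM in 16-month WT, and Ifi204 at 431 and 341 against 186 CPM. Between the WT libraries, 16 months against unstated age, Cst7 stood at 392.3 against 113 CPM and the list median, 0.41, lay inside the central 95% of random lists. Cells closest to an Spp1-led cluster made up 40.9% (38.7 to 43.2) of microglia-like cells at 16 months, 7.38% (6.18 to 8.72) at 9 months, 3.48% (2.61 to 4.56) in 16-month WT and 0.062% (0.013 to 0.181) in WT whole brain. The profile for that call came from the 16-month APP/PS1 library itself.

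**Figure D5:**
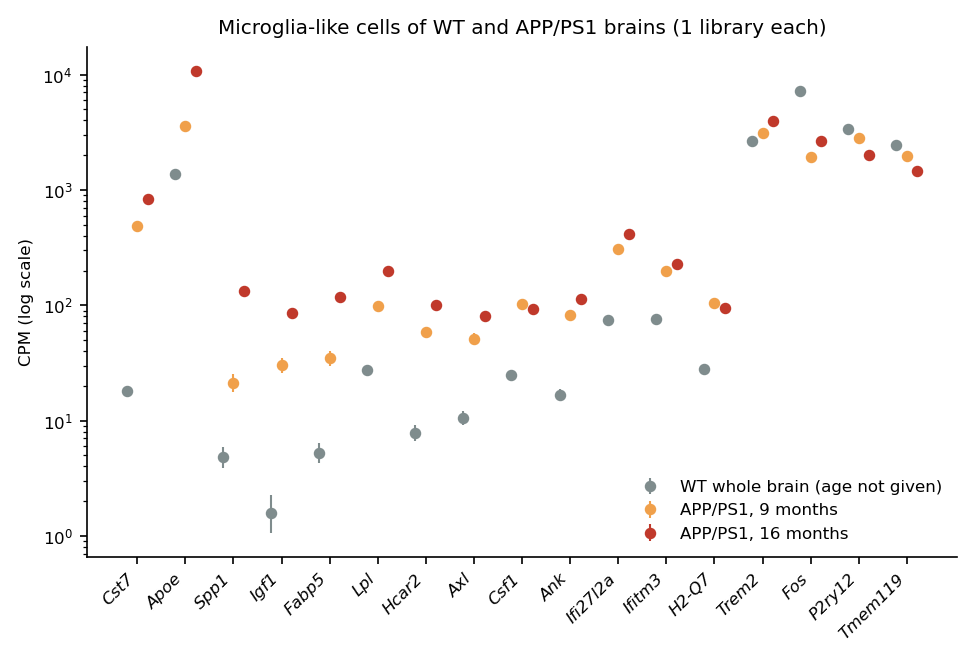
CPM (log scale, vertical axis) of 17 genes in microglia-like cells of WT whole brain and of APP/PS1 brain at 9 and 16 months, 1 point per library with its 95% Poisson interval. Cst7 goes from 17.9 CPM in WT to 489 CPM at 9 and 838 CPM at 16 months, and Apoe from 1362 to 3563 and 10843 CPM.

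Genes named most often lie at these places of GRCm38, counted from 1. Apoe (ENSMUSG00000002985.16) spans chromosome 7 from 19696109 to 19699188 and Apoc1 (ENSMUSG00000040564.14) 19689481 to 19692660 beside it, both on the minus strand. Cst7 (ENSMUSG00000068129.5) spans chromosome 2 from 150570415 to 150578944 and Spp1 (ENSMUSG00000029304.14) chromosome 5 from 104435118 to 104441050. H2-Aa (ENSMUSG00000036594.15) lies on chromosome 17 from 34282744 to 34287823, Cd209f (ENSMUSG00000051906.15) on chromosome 8 from 4102787 to 4105835, Fos (ENSMUSG00000021250.13) on chromosome 12 from 85473890 to 85477273 and P2ry12 (ENSMUSG00000036353.13) on chromosome 3 from 59216272 to 59262871.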

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

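The comparison of barcodes with the deleter library was chosen after the result was seen, and the comparison of lists between the Apoc1-led cells and deleter cells before it.

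A pair of gene groups went opposite ways in different tissues, each beyond the central range of random lists. Neutrophil markers in BAM-like cells had a median log2 ratio of 1.19 with actinomycin D in dura and -0.59 in choroid plexus. NF-kB and cytokine genes had 0.71 in brain microglia-like cells and -0.34 in choroid plexus BAM-like cells of the Irf8 deleter. The difference between tissues was not tested in either case, since each value rests on 1 library against 1. In brain 13 of 18 NF-kB members were higher, 8 of them with a log2 ratio of 1 or more, such as Ccl7, Il1b and Ccl2, and in choroid plexus Il1b was among the genes with the lowest ratios.

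Among the unnamed clusters, those of 3 kinds are described here. They were in no named class and entered comparisons of named classes over all genes only as alternatives, if at all. Apoc1-led cells made up 4.20% (3.69 to 4.77) of Irf8 control brain, 231 cells. Spp1-led cells made up 8.40% (7.56 to 9.29) of 16-month APP/PS1 brain, 339 cells, and entered the comparison with 16-month WT brain over 3999 genes. Apoc1-led cells made up 7.98% (6.88 to 9.19) of Irf8 deleter choroid plexus, 176 cells.

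The Apoc1-led cells of Irf8 control brain shared part of the profile of the microglia-like cells of the deleter. Relative to control microglia-like cells, the border core list had a median of 3.10 in the cluster and 2.97 in the deleter cells, the homeostatic list -1.25 (-1.34 to -1.20) and -1.59, and MHC class II -1.17 (-1.48 to -0.79) and -0.33. Barcodes shared with the deleter brain library made up 0.433% of these cells (0.011 to 2.39), against 0.893% of the other cells, which argues against barcodes read from that library. The interferon list had a median of 1.05 (0.858 to 1.35) in these cells and 1.38 in deleter cells, so deleter cells carried into the control library cannot be told apart from cells of the control mouse by this list. Irf8-linked genes had a median of -0.748 (-0.834 to -0.67) in these cells and -0.845 in deleter cells. Monocyte-derived genes lay at -0.34 to 0.39 in the cluster against 1.005 in deleter cells. Such cells may also occur without Cre, which was not tested.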

How the results depend on the processing

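Doubled and zero naming margins and the settings with or without Spp1-led, Spp1-closest or Apoc1-led cells were chosen after the data had been seen, as was the test of actinomycin D over pairs of tissues with its alternatives. Unless stated, the cause of a change was not tested.

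Between dura and choroid plexus 1574 genes passed. The DESeq2 Wald test passed 979, the fit without the pair term 684, a resolution of 2.0 gave 975, and leaving out 1 pair gave 641 to 1229, with fewer samples. Shared genes were not counted. Between choroid plexus and brain microglia-like cells 2561 genes passed, and 1014 (Wald), 1297 (no pair term) and 1253 (cell by cell) under alternatives. The Irf8 deleter pair entered that cell by cell test but not the main one. For actinomycin D over pairs of tissues 724 genes passed, and 1431 (no filter), 52 (no tissue term), 395 (Wald), 1089 (cell by cell) and 1188 (margins 0). With an estimated correlation camera passed 0 of the 8 and 0 of the 15 lists.

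Immediate early medians with actinomycin D were -3.91 (dura) without ribosomal and mitochondrial genes and -4.02 (dura), -4.31 (choroid plexus BAM-like) and -5.47 (microglia-like) with a pseudocount of 1 CPM. Choroid plexus BAM-like cells had -4.02 at a resolution of 2.0, -4.06 cell by cell and -4.02 with margins doubled, and microglia-like cells -5.10 when thinned. For Irf8 in brain the homeostatic median was -1.38 (TMM), -1.48 (no ribosomal genes), -1.54 (per-cell means), -1.56 (thinned), -1.53 (resolution 2.0), -1.37 (cell by cell), -1.55 (doublets kept) and -1.55 (with Apoc1-led cells). The border core median was 3.07 (TMM), 3.19 (no ribosomal genes), 4.68 (pseudocount 1), 1.87 (all detected members), 2.65 (cell by cell) and 2.53 (with Apoc1-led cells). MHC class II in choroid plexus was -2.17 (TMM), -1.65 (resolution 0.5), -1.80 (cell by cell), -1.59 (margins doubled) and -2.11 (margins 0).

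The disease-associated median at 16 months against 16-month WT was 0.80 without ribosomal genes and 0.58 without Spp1-closest cells. Against WT whole brain it was 1.76 (TMM), 1.78 (no ribosomal genes), 1.18 (per-cell means), 1.26 (thinned), 1.91 (resolution 0.5), 1.68 (resolution 2.0), 1.76 (cell by cell), 1.37 (doublets kept), 1.69 (margins 0) and 1.91 (with Spp1-led cells). At 9 months it was 0.88 (no ribosomal genes), 0.68 (per-cell means), 0.69 (thinned), 0.75 (cell by cell), 0.72 (doublets kept) and 0.70 (margins 0).

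BAM-like shares in WT dura were 28.0% (resolution 2.0), 26.0% (cell by cell), 27.5% (doublets kept), 29.1% (all barcodes) and 37.4% (margins 0). In WT choroid plexus they were 45.5% (resolution 0.5), 38.1% (cell by cell), 61.2% (all barcodes) and 60.6% (margins doubled), and in subdural meninges 14.9% (resolution 2.0), 21.7% (doublets kept), 21.7% (all barcodes) and 25.2% (margins 0). Microglia-like cells in WT brain were 77.6% (doublets kept), 77.6% (all barcodes) and 77.8% (margins 0).

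Directions turned in a few settings. With actinomycin D, the dura cell cycle median was 0.80 at a resolution of 0.5. In microglia-like cells the border core median was 0.11 cell by cell and 0.17 with margins 0, the homeostatic median -0.13, P2ry12 -0.13 and Pf4 0.44 with margins 0, Pf4 0.69 cell by cell, and the interferon median 0.005 with margins 0. In BAM-like cells of WT choroid plexus against brain a resolution of 0.5 gave 0.017 for the border core, -0.44 for MHC class II, -0.38 for H2-Aa and -0.14 for Cd74. In APP/PS1 against WT whole brain the MHC class II median was -0.226 at 9 and -0.489 at 16 months with doublets kept, and -0.243 and -0.588 with margins 0. Among the 195 genes of the text, 4 turned in at least 1 setting, and among all 997 genes chosen by the rule 58 did, as did 18 of 86 further lists. For genes with a test, 885 of 943 values under alternatives kept direction and side of the threshold, 53 lost the call and 5 gained it. For genes without a test, 735 of 1214 stayed inside the counting interval and 474 moved.

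Doubled margins left too few named cells for choroid plexus microglia-like cells of the Irf8 control, for BAM-like cells of actinomycin D dura and for microglia-like cells of deleter brain, so comparisons of these libraries gave no value and the test of dura and choroid plexus kept 2 pairs. BAM-like cells of choroid plexus and brain gave 2 or more pairs only cell by cell and with doublets kept (111 genes rose and 110.0 fell by edgeR). With doublets kept the pairs were WT and Irf8 deleter.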

Other observations

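The tests of a mixture, of age and of other splits were chosen after the result was seen, and the test of dissociation before it.

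Between the APP/PS1 libraries, the disease-associated list was higher at 16 than at 9 months in 26 of 27 members (median log2 ratio 0.59, 0.50 to 0.63). Spp1 stood at 132 against 21.3 CPM, Fabp5 at 118 against 34.5 CPM, Apoe at 10843 against 3563 CPM and the integrin Itgb3 at 80.6 against 32.96 CPM. The lipid efflux list, of which Apoe is a member, was lower in 5 of 6 members (median -0.29). The chaperones Hspa1a (42.5 against 1299 CPM) and Hspb1 (17.7 against 208 CPM) and the zinc finger factor Klf2 (599 against 2161 CPM) were lower at 16 months. Markers of other cells moved as well, with medians of -1.56 for neutrophil, -0.57 for monocyte and 0.40 for dendritic markers. Age and dissociation are not separated here.

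Cells outside the macrophage classes differed between libraries as well. Dendritic-like cells made up 10.5% (9.62 to 11.4) of dura with the standard protocol and 3.31% (2.75 to 3.96) with actinomycin D, and in choroid plexus 12.8% (11.3 to 14.4) and 5.23% (4.35 to 6.22). Cells in unnamed clusters went from 5.20% to 13.1% in dura and from 10.2% to 18.6% in choroid plexus, so dendritic cells left unnamed could account for part or all of the lower share. In Irf8 deleter brain B-like cells made up 6.96% (6.35 to 7.61), NK-like cells 5.95% (5.38 to 6.56) and monocyte-like cells 3.84% (3.38 to 4.34), against 1.31%, 1.49% and 0.728% in control brain.

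Choroid plexus microglia-like cells carried Apoe, Spp1 and Cst7 as well as border genes such as Pf4, and a mixture with RNA or cells of BAM-like type could give both. Mixing brain microglia-like with BAM-like profiles in the share that fitted best left the disease-associated genes above the mixture by 1.074 (1.013 to 1.126) on the log2 scale in WT, 0.895 (0.855 to 0.94) with actinomycin D, 0.645 (0.572 to 0.686) with the standard protocol and 0.51 (0.385 to 0.642) in Irf8 control. The border core genes that were not naming markers lay above it by 0.253 (-0.118 to 0.489) in WT and 0.286 (-0.207 to 0.43) with actinomycin D. They lay at -0.346 (-0.656 to -0.013) with the standard protocol and -0.482 (-0.615 to -0.225) in Irf8 control. Those medians were within 0.5 of the mixture, but the intervals of the standard and Irf8 control libraries reached past that bound. The disease-associated genes exceeded the bound of 0.5 beyond the interval in 3 libraries but not in Irf8 control. A mixture cannot be told apart from a state of these cells because the bound was set for all 4 libraries and the fitted share ran from 8.08 to 43.4% between them.

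The higher disease-associated list in APP/PS1 microglia-like cells was weighed against dissociation and age. Members were taken that actinomycin D left within 0.5 on the log2 scale in choroid plexus microglia-like cells (118 against 69 cells). Their medians were 1.22 at 16 months (19 members) and 0.75 at 9 months (18 members), above the bound of 0.5. Those choroid plexus cells had a fitted BAM-like share of 8.08% with actinomycin D and 43.4% with the standard protocol. The choice of members is not separated from that mixture, so no conclusion on dissociation is drawn. Against WT of 16 months the 3 measured members, B2m, Ctsz and Cst7, had a median of 0.76 at 16 months. For these 3 genes at 16 months that argues against age as the whole cause. At 9 months their median was 0.44, and between the WT libraries it was 0.41. The other members of the list were not measured there, and cells closest to the Spp1-led profile of the same APP/PS1 library were included. The amyloid model may raise the disease-associated list, a hypothesis that rests on 1 library per age, and batch and dissociation stay open.

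Between dura and choroid plexus the real split of the 6 libraries gave 1574 genes by edgeR and the highest of the other splits 0. The 10 splits, of which 1 gave as many genes, are too few for a share under 0.05.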
